A study of Mus musculus with 26 samples.

How the data were processed

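RNA was measured in 26 mouse libraries of untreated animals, 12 from retina and 14 from the optic nerve. Per the labels, poly(A) RNA was amplified with an ultra-low input kit after immunoprecipitation of astrocyte RNA, with retinal input libraries taken alongside. Per the submitters' processing notes, reads were quantified with Salmon 1.6.0 against mm10. The deposited table holds the estimated count per gene that the authors obtained, for 54532 genes. Symbols were matched for 54409 of the 54532 genes from the GENCODE M21 annotation, and 22279 genes had 0 counts in every library. No column of the table was left without a sample.

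Libraries were grouped by the labels into retina IP (6), retina input (6), ONH IP (7) and ONP IP (7), and the sequencing batch was taken from the labels. Batch 1 held 12 libraries and batch 2 held 14. Groups, comparisons, gene lists and most alternatives were chosen before the data were examined. Counts per library ranged from 11164619 to 27431026.

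Differences were tested in R 4.3.3 with edgeR 4.0.16, using TMM size factors, filterByExpr with a minimum count of 10 and a minimum total of 15, and the quasi-likelihood F test. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Retina IP was tested against retina input on the 12 retinal libraries without covariates. The 3 comparisons between regions were fitted on all 20 IP libraries with a batch term, which the bridging libraries make estimable. Genes set apart from both optic nerve regions had to pass in both tests in the same direction. The overlap was set against 20 simulations of unchanged groups and 20 splits of the retinal libraries into sets of 3. After filtering over all 26 libraries, 17173 genes were kept for levels in CPM.

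Gene lists numbered 38, with 607 genes in all and 8 to 32 genes each, 14 for cell types and 24 for functions. Each list was tested with camera of limma 3.58.1 at a preset correlation of 0.01 and again with the correlation estimated from the data, and its members were also adjusted over the list alone. Named genes were the 10 largest changes per direction with a real symbol and a mean of at least 10 CPM in the higher group. The libraries of the 2 groups also had to lie apart without overlap, and for both optic nerve regions, apart from each. To these were added up to 3 called members of a list in the majority direction and up to 2 the other way, and a set of genes fixed beforehand. Some genes that met these rules are left out of the text. Other list members are given as values with their test. Where a group held 3 or fewer counts, a ratio with a 95% Poisson counting interval takes the place of the fitted fold.

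Alternatives tried were RLE size factors, no low-count filter, DESeq2 1.42.0, limma-voom, all 26 libraries in one fit, a replicate block, no batch term, single batches, only the groups compared, a 2-fold threshold and the omission of each library. Log2 values were rounded to 2 decimals and other values to 3 significant digits. Figures were drawn with matplotlib 3.10.9.

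The tests were tested on simulated data with the real library sizes and fitted dispersions, with 100 genes changed 2-fold and 100 changed 4-fold. Of these, 1 and 32 were called for retina IP against input, 7 and 37 for retina against ONH, 7 and 41 for retina against ONP, and 28 and 72 for ONH against ONP. No changed gene was called in the wrong direction. Among unchanged genes, 1, 5, 3 and 3 were called in the same order. Each grouping was also set against 99 other arrangements of the same libraries, 100 splits with the real one included.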

Results

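RNA was measured in 26 mouse libraries that fall into 4 groups. Retinal RNA was sequenced as 6 libraries of immunoprecipitated (IP) RNA, enriched for the RNA of astrocytes, and as 6 input libraries. IP RNA of the optic nerve head (ONH), where axons leave the eye, gave 7 libraries, and IP RNA of the myelinated optic nerve proper (ONP) gave 7. All animals were untreated. The 12 retinal libraries formed sequencing batch 2 together with 1 ONH and 1 ONP library, both replicate 7 and here called the bridging libraries. The other 12 optic nerve libraries formed batch 1. Total counts per library ranged from 11164619 to 18417001 in retina input, from 14703195 to 24966236 in retina IP, from 14812762 to 26407745 in ONH IP and from 14051088 to 27431026 in ONP IP. Levels are given in CPM, counts scaled to library size, and differences as log2 fold changes with their standard error (SE). The labels do not say whether each library came from a separate animal, so p-values measure the spread between these libraries. Mitochondrially encoded transcripts took 2.79% to 15.2% of counts in the input libraries and 0.155% to 2.23% in the retinal IP libraries.

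The first comparison asked which transcripts the immunoprecipitation enriched over retinal input. Astrocyte genes averaged higher in the IP libraries, and photoreceptor, microglia and ribosomal protein genes averaged lower, but edgeR called no single gene over all genes. Gfap, the intermediate filament of astrocytes, averaged 1703 CPM in IP and 313.6 CPM in input (log2 fold change 2.56, SE 0.713, adjusted p = 0.0701). Pax8 (ENSMUSG00000026976, mm10 chromosome 2, 24420560 to 24475599), a paired-box transcription factor and the marker the study put forward, averaged 175.9 and 25.96 CPM (2.89, SE 0.672, adjusted p = 0.057). Pax2, which marks the optic stalk and the astrocytes derived from it, had a log2 fold change of 3.49 (adjusted p = 0.0619). Pdgfra, the receptor through which neurons recruit retinal astrocytes, had one of 2.29 (adjusted p = 0.0663), and Slc1a3, an astrocyte glutamate transporter, one of 2.41 (adjusted p = 0.059). Values for S100b and Aldh1l1, both common astrocyte markers, were 1.86 (adjusted p = 0.146) and 2.11 (adjusted p = 0.0866). The water channel gene Aqp4 hardly differed (0.10, adjusted p = 0.957), and its sign turned under DESeq2 and under the other size factors. DESeq2 and a fit of all 26 libraries did call Gfap, Pax8, Pax2, Pdgfra, Slc1a3 and Aldh1l1 higher in IP, and the fit of all 26 libraries also S100b.

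Of 23 measured genes shared by astrocytes across the nervous system, 14 were higher in IP and 0 lower when adjusted over the list alone (edgeR), and 0 passed over all genes. They included Mlc1, a membrane protein of astrocyte endfeet (2.86, adjusted p = 0.057), the transcription factor Sox9 (2.74, adjusted p = 0.057) and the gap junction gene Gja1 (3.02, adjusted p = 0.0663). The set test camera ranked this list above other genes (adjusted p = 3.7e-07), but not with an estimated correlation (adjusted p = 0.322). Potassium, water and pH genes had 8 of 19 members higher and 0 lower when adjusted over the list alone. Their camera adjusted p was 0.000553, and 0.349 with an estimated correlation. Interferon and MHC class I genes had 8 of 15 members higher when adjusted over the list alone, such as the antigen-presenting H2-K1 (1.66) and the interferon-induced Ifit3 (1.74), with a camera adjusted p of 5.53e-06, and 0.372 with an estimated correlation. Basement membrane and matrix genes had 9 of 22 members higher when adjusted over the list alone, including agrin (Agrn, 2.11) and brevican (Bcan, 2.66); camera gave an adjusted p of 0.000116, and 0.366 with an estimated correlation. Eye-field and glial transcription factors had 11 of 25 members higher when adjusted over the list alone, among them the eye-field gene Rax (2.24). Their camera adjusted p was 0.00196, and 0.366 with an estimated correlation. Cholesterol synthesis had 0 of 20 members past the test when adjusted over the list alone, but 18 of 20 estimates were positive (camera adjusted p = 0.00028, and 0.316 with an estimated correlation).

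Transcripts of other retinal cells did not move together. Müller glia genes had 4 of 8 members higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.0472, and 0.433 with an estimated correlation). Rlbp1, the retinaldehyde-binding protein of these cells, had a log2 fold change of 1.78 (adjusted p = 0.071, called by DESeq2 and the fit of all 26 libraries), and Glul, glutamine synthetase, one of 0.99 (adjusted p = 0.217). All 15 rod genes had negative estimates, 9 of them at an unadjusted p under 0.05, and 0 passed when adjusted over the list alone (camera adjusted p = 2.25e-05, and 0.431 with an estimated correlation). Retinal ganglion cell genes had a median of -0.44, with 0 of 12 past the test when adjusted over the list alone (camera adjusted p = 0.00153, and 0.437 with an estimated correlation). Without input replicates 1 and 2 the ganglion cell list did not pass camera (adjusted p = 0.0652). Nefm, a neurofilament gene of these neurons, averaged 416.7 CPM in IP and 465.4 CPM in input. Microglia genes had 6 of 12 members lower when adjusted over the list alone, among them the signalling adaptor Tyrobp (-3.65, adjusted p = 0.057), with a camera adjusted p of 2.36e-05, and 0.316 with an estimated correlation. Cytosolic ribosomal protein genes had 16 of 20 members lower when adjusted over the list alone, such as Rps19 (-2.52), with a camera adjusted p of 2.91e-10, and 0.366 with an estimated correlation. Without input replicates 1 and 2, Rps19 was at -1.18 and Tyrobp at -1.58. Those 2 libraries had 8.165% and 15.19% mitochondrial counts, and counts for 16782 and 17082 genes against 19835 to 20702 in the other inputs. Oxidative phosphorylation genes had 11 of 25 members lower when adjusted over the list alone, including Cox6c of complex IV (-1.89), with a camera adjusted p of 0.000168, and 0.431 with an estimated correlation. Mbp, the myelin basic protein gene, did not differ (0.22, adjusted p = 0.906).

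Over all 15181 genes tested, edgeR's quasi-likelihood test called 0 genes higher and 0 lower at an adjusted p under 0.05, with a smallest adjusted p of 0.057. At an unadjusted p under 0.05, 1771 genes were higher and 1585 lower. DESeq2 called 969 higher and 1103 lower, and limma-voom called 0 and 0. Leaving out retina IP replicate 1 gave 341 higher and 40 lower, leaving out retina IP replicate 5 gave 226 and 20, and leaving out retina input replicate 2 gave 0 and 1. The retinal IP libraries were uneven. Pax8 stood at 30.2, 253, 310, 377, 42.6 and 42.4 CPM in IP replicates 1 to 6, against 7.27 to 34.2 CPM in the inputs, and Gfap at 361, 2810, 1570, 3760, 796 and 924 CPM. The median ratio of ganglion cell genes to the input mean was 0.982, 0.405, 0.278, 0.195, 1.13 and 1.14 in the same order.

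**Figure D1:**
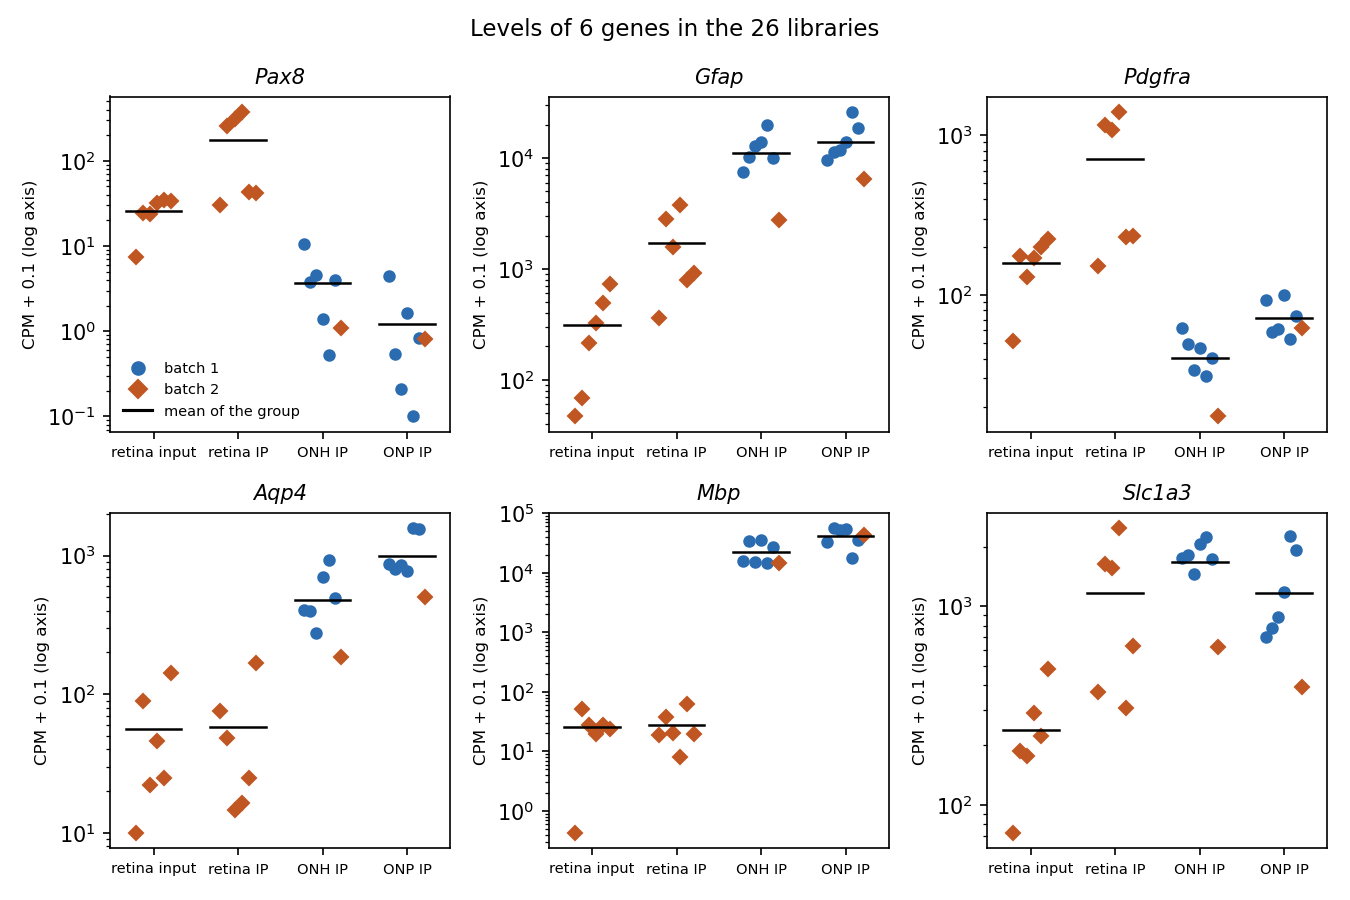
CPM of 6 genes on a log axis (0.1 added) in every library, by group, with circles for batch 1, diamonds for batch 2 and lines for group means. Pax8 averaged 175.9 CPM in retina IP, 25.96 in retina input, 3.60 in ONH IP and 1.13 in ONP IP.

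**Figure D2:**
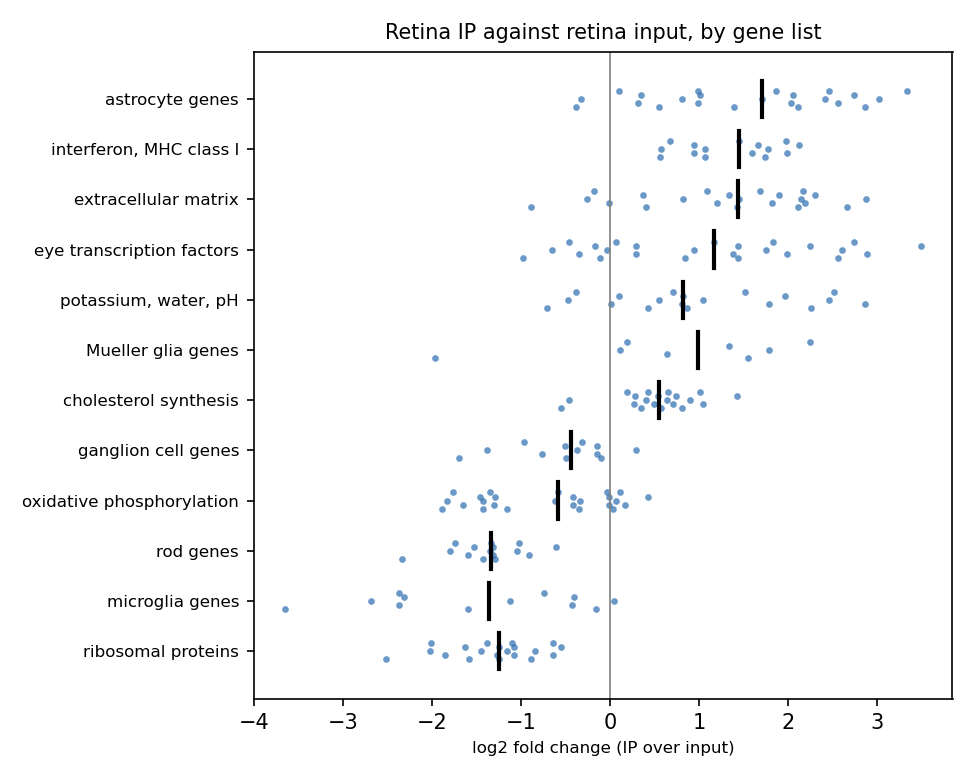
Log2 fold change of retina IP over retina input for each measured member of 12 gene lists, with list medians as black bars; members with 3 or fewer counts in a group are left out. The astrocyte genes lie mostly above 0, and all 20 ribosomal protein genes lie below it.

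The second comparison asked how retinal IP RNA differed from ONH IP RNA. Pax8 rose in the retina, together with Pdgfra, Angpt4 and most glycolysis genes, and all oligodendrocyte genes measured and most microglia, fibroblast and reactive glia genes fell. Pax8 averaged 175.9 CPM in retina and 3.60 CPM in ONH (log2 fold change 6.98, SE 1.80, adjusted p = 0.00567), and stood at 0.999 CPM in the bridging ONH library. The call of Pax8 ended without ONH replicate 7 (6.22, adjusted p = 0.0775) and under limma-voom (6.17, adjusted p = 0.0546). Pdgfra rose by 4.84 (adjusted p = 0.000317), and Angpt4, an angiopoietin that acts on vessels, rose by 9.55 (adjusted p = 0.00014). The scavenger receptor gene Cd36, which takes up fatty acids, rose by 6.91 (adjusted p = 0.00708), but not without ONH replicate 7 (5.50, adjusted p = 0.0947). Ackr2, a chemokine-scavenging receptor, had 9861 counts in retina and 1 in ONH, a ratio of 11700 with a 95% counting interval of 2100 to 462000, which covers counting error only. Glutamate and GABA handling genes were split, with 5 of 16 higher and 5 lower, also when adjusted over the list alone (camera adjusted p = 0.151, and 0.447 with an estimated correlation). The GABA transporter gene Slc6a11 (5.13, adjusted p = 0.000147) and the transaminase gene Abat (3.19, adjusted p = 2.9e-07) rose. Another GABA transporter gene, Slc6a13, fell (-4.78, adjusted p = 0.00326), but not without ONH replicate 7 (-1.66, adjusted p = 0.494). Growth factor genes had 0 of 15 members higher and 7 lower, and 1 and 7 when adjusted over the list alone (camera adjusted p = 0.0214, and 0.234 with an estimated correlation).

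General astrocyte genes were split, with 4 of 28 higher and 13 lower in retina over all genes and the same counts when adjusted over the list alone (camera adjusted p = 0.0363, and 0.592 with an estimated correlation). Aldoc, an astrocyte aldolase, rose by 3.45 (adjusted p = 0.000196), and the growth factor receptor gene Fgfr3 (-7.38, adjusted p = 5.16e-08) and the adhesion gene Hepacam (-5.07, adjusted p = 3.66e-06) fell. Aqp4 fell with a log2 fold change of -1.85 (adjusted p = 0.0375), which ended without ONH replicate 7 (-2.07, adjusted p = 0.116) or ONP replicate 7 (-1.68, adjusted p = 0.163). Leaving out ONP replicate 4 or retina IP replicates 2, 4 or 5 also ended the call of Aqp4 (adjusted p from 0.0532 to 0.0709). Glul rose by 1.68 (adjusted p = 0.00798) and Rlbp1 by 1.92 (adjusted p = 0.0324). Without ONP replicate 7 both calls ended (Glul adjusted p = 0.0757, Rlbp1 adjusted p = 0.296), as did that of Glul without ONH replicate 7 (adjusted p = 0.0626). Gfap (-1.12, adjusted p = 0.179), Pax2 (1.90, adjusted p = 0.142), S100b (-0.89, adjusted p = 0.363), Slc1a3 (0.99, adjusted p = 0.253) and Aldh1l1 (0.24, adjusted p = 0.788) did not pass. These estimates average over uneven retinal IP libraries. S100b stood at 1369 to 1651 CPM in IP replicates 2 to 4 and at 180.6 to 217.3 CPM in replicates 1, 5 and 6. In ONH it ran from 865.1 to 1864 CPM. Slc1a3 stood at 1563 to 2483 CPM and at 309.3 to 630.6 CPM in the same retinal sets, while Aqp4 did not follow this split. How far this unevenness shaped the estimates was not tested. The signs for S100b, Slc1a3 and Aldh1l1 turned under other treatments of batch. Without a batch term Gfap (-2.66, adjusted p = 0.000204) and Aldh1l1 (-1.11, adjusted p = 0.0412) were called lower in retina. Over all alternatives the adjusted p ran from 4.93e-05 to 0.848 for Gfap and from 0.0113 to 0.891 for Aldh1l1.

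Glycolysis and lactate genes had 15 of 21 members higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 1.6e-05, and 0.304 with an estimated correlation). The 2 that fell were the hexokinase gene Hk2 (-4.49, adjusted p = 2.06e-07) and the lactate transporter gene Slc16a1 (-2.66, adjusted p = 2e-05). In mean log2 CPM the list stood at 8.882 in retina IP, 8.467 in retina input and 8 in ONH. Its median log2 fold change of retina IP over input was 0.30. Part of the difference was thus present in whole retina. Cholesterol synthesis had 8 of 20 members higher and 0 lower, also when adjusted over the list alone, among them Insig1, which restrains the pathway (1.93, adjusted p = 0.00057); camera gave an adjusted p of 6.82e-05, and 0.372 with an estimated correlation. All 13 oligodendrocyte genes fell, also when adjusted over the list alone (camera adjusted p = 1.62e-14, and 0.234 with an estimated correlation). Mbp fell from 22350 CPM in ONH to 27.88 CPM in retina (-9.36, adjusted p = 2.87e-09). The oligodendrocyte lineage factor Sox10 fell as well (-9.46, adjusted p = 5.65e-11). Microglia genes had 11 of 12 members lower, also when adjusted over the list alone (camera adjusted p = 0.000208, and 0.433 with an estimated correlation), such as the complement gene C1qa (-4.57, adjusted p = 1.65e-05). Fibroblast genes had 9 of 10 members lower, also when adjusted over the list alone, among them the collagen gene Col3a1 (-8.21, adjusted p = 5.8e-07), with a camera adjusted p of 0.00011, and 0.349 with an estimated correlation. Reactive astrocyte and complement genes had 12 of 19 members lower over all genes and 16 when adjusted over the list alone, including the heat-shock gene Hspb1 (-3.67, adjusted p = 7.27e-08); camera gave an adjusted p of 4.15e-07, and 0.258 with an estimated correlation. Interferon and MHC class I genes had 8 of 15 members lower over all genes and 9 when adjusted over the list alone (camera adjusted p = 0.00148, and 0.516 with an estimated correlation).

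Neuronal and photoreceptor genes also separated these libraries. Ganglion cell genes had 11 of 12 members higher in retina, also when adjusted over the list alone (camera adjusted p = 1.72e-06, and 0.349 with an estimated correlation). Nefm rose by 4.73 (adjusted p = 0.000469), while against retinal input it was not enriched. Rod genes had 15 of 15 members lower, also when adjusted over the list alone (camera adjusted p = 1.98e-08, and 0.349 with an estimated correlation). This result depended on the bridging ONH library. The median rod gene stood at 2110 CPM in that library and at 9.32 CPM in the other ONH libraries. Without that library the rod list did not pass camera (adjusted p = 0.0861), and under other treatments of batch its direction turned to higher in retina.

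edgeR called 2080 genes higher and 3452 lower in retina than in ONH, of 16355 tested, with batch as a term. Without ONP replicate 7, which informs that term, the counts were 722 and 2262. In batch 2 alone, with 1 ONH library and so no measure of spread between ONH libraries, 121 genes were higher and 697 lower, and Pax8 had a log2 fold change of 7.66 (adjusted p = 0.12). Because 12 of the 14 optic nerve libraries were in the other batch, these calls rest on the bridging libraries. Sex went with batch as well. A sum of 4 Y-linked genes was at least 702 counts in every batch 1 library and at most 1 in batch 2.

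The third comparison set retinal against ONP IP RNA. Pax8, Angpt4 and most glycolysis genes rose in retina, and all oligodendrocyte genes measured, Aqp4 and most reactive glia genes fell. Pax8 averaged 1.13 CPM in ONP (log2 fold change 8.57, SE 1.89, adjusted p = 0.00172), and 0.721 CPM in the bridging ONP library. Angpt4 rose by 11.28 (adjusted p = 2.55e-05), Cd36 by 10.34 (adjusted p = 0.000663) and Pdgfra by 3.94 (adjusted p = 0.000916), the last not with only the groups compared (3.62, adjusted p = 0.0545; over all alternatives 2.29e-08 to 0.18). Hypoxia and angiogenic genes had 7 of 18 members higher and 3 lower, also when adjusted over the list alone, and did not pass camera (adjusted p = 0.0772, and 0.386 with an estimated correlation). Among them the vasodilator peptide gene Adm rose by 4.70 (adjusted p = 0.000723) and the endothelial growth factor gene Vegfa by 2.94 (adjusted p = 0.00223), the latter not without ONP replicate 7 (2.59, adjusted p = 0.0765). The stress-response gene Ndrg1 (-4.24, adjusted p = 2.09e-06) and the angiopoietin gene Angpt1 (-3.36, adjusted p = 8.05e-06) fell. Slc6a11 rose by 4.52 (adjusted p = 0.000331) and the eye-field factor gene Vax2 by 3.65 (adjusted p = 0.000125). Chrna6, a nicotinic receptor subunit of retinal neurons, had 53505 counts in retina IP and 2 in ONP, a ratio of 29200 with a 95% counting interval of 8080 to 241000. Chrna6 averaged 427.4 CPM in retina IP and 434.5 CPM in retina input.

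General astrocyte genes had 2 of 28 members higher and 14 lower over all genes, and 3 and 14 when adjusted over the list alone (camera adjusted p = 0.00767, and 0.516 with an estimated correlation). Aqp4 averaged 57.58 CPM in retina and 990.1 CPM in ONP (-2.93, adjusted p = 0.00151), and passed in every fit that left out 1 library except that without ONP replicate 7 (-2.70, adjusted p = 0.0624). The glutamate transporter gene Slc1a2 fell as well (-2.25, adjusted p = 0.00045). Gfap had an adjusted p of 0.0487 (-1.55), and 16 of the 20 fits that left out 1 library did not call it, with the weakest value without ONP replicate 7 (adjusted p = 0.529). Glul (1.66, adjusted p = 0.00904) and Rlbp1 (3.46, adjusted p = 0.00195) rose, and neither passed without ONP replicate 7 (Glul adjusted p = 0.131, Rlbp1 adjusted p = 0.0835). Pax2 (2.51, adjusted p = 0.054) and Slc1a3 (1.52, adjusted p = 0.0934) did not pass. Both passed without retina IP replicate 1 (Pax2 adjusted p = 0.0208, Slc1a3 adjusted p = 0.0483) or replicate 5 (Pax2 adjusted p = 0.0466, Slc1a3 adjusted p = 0.0383), and Pax2 also without replicate 6 (adjusted p = 0.0441). DESeq2 called both higher in retina, and Pax2 was called higher without a batch term as well. S100b (-0.69, adjusted p = 0.464) and Aldh1l1 (0.11, adjusted p = 0.915) did not pass, and the signs of Slc1a3 and Aldh1l1 turned under other treatments of batch. As against ONH, these estimates average over uneven retinal IP libraries. Without a batch term Aldh1l1 was called lower in retina (-1.25, adjusted p = 0.0226, and from 0.00656 to 0.954 over all alternatives).

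Glycolysis and lactate genes had 14 of 21 members higher and 2 lower, also when adjusted over the list alone (camera adjusted p = 9.95e-07, and 0.258 with an estimated correlation), with lactate dehydrogenase A (Ldha) up by 2.06 (adjusted p = 0.000393). Retina input also averaged above ONP in this list, at a mean log2 CPM of 8.467 against 7.677. Eye-field and glial transcription factors had 15 of 29 members higher and 3 lower over all genes, and 16 and 4 when adjusted over the list alone (camera adjusted p = 0.0192, and 0.406 with an estimated correlation). Without ONH replicate 7, which is in neither group compared, this list did not pass camera (adjusted p = 0.138). All 13 oligodendrocyte genes fell, also when adjusted over the list alone (camera adjusted p = 6.41e-17, and 0.227 with an estimated correlation), with Mbp at -10.29 (adjusted p = 6.75e-10) and the membrane protein gene Opalin at -11.51 (adjusted p = 7.36e-11). Oligodendrocyte precursor genes had 6 of 8 members lower and 1 higher, also when adjusted over the list alone, the 1 being Pdgfra (camera adjusted p = 0.000243, and 0.264 with an estimated correlation). All 12 microglia genes fell, also when adjusted over the list alone (camera adjusted p = 1.17e-05, and 0.372 with an estimated correlation). Reactive astrocyte and complement genes had 12 of 19 members lower and 0 higher, also when adjusted over the list alone (camera adjusted p = 7.21e-06, and 0.304 with an estimated correlation), among them complement C3 (-5.23, adjusted p = 2.57e-07). All 12 ganglion cell genes rose, also when adjusted over the list alone (camera adjusted p = 1.04e-07, and 0.322 with an estimated correlation), with Nefm at 6.48 (adjusted p = 5.69e-05).

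edgeR called 2116 genes higher and 3255 lower in retina than in ONP, of 16355 tested. Without ONP replicate 7 the counts were 567 and 1588. In batch 2 alone, with 1 ONP library and so no measure of spread between ONP libraries, 783 genes were higher and 907 lower, and Pax8 had a log2 fold change of 8.18 (adjusted p = 0.075).

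**Figure D3:**
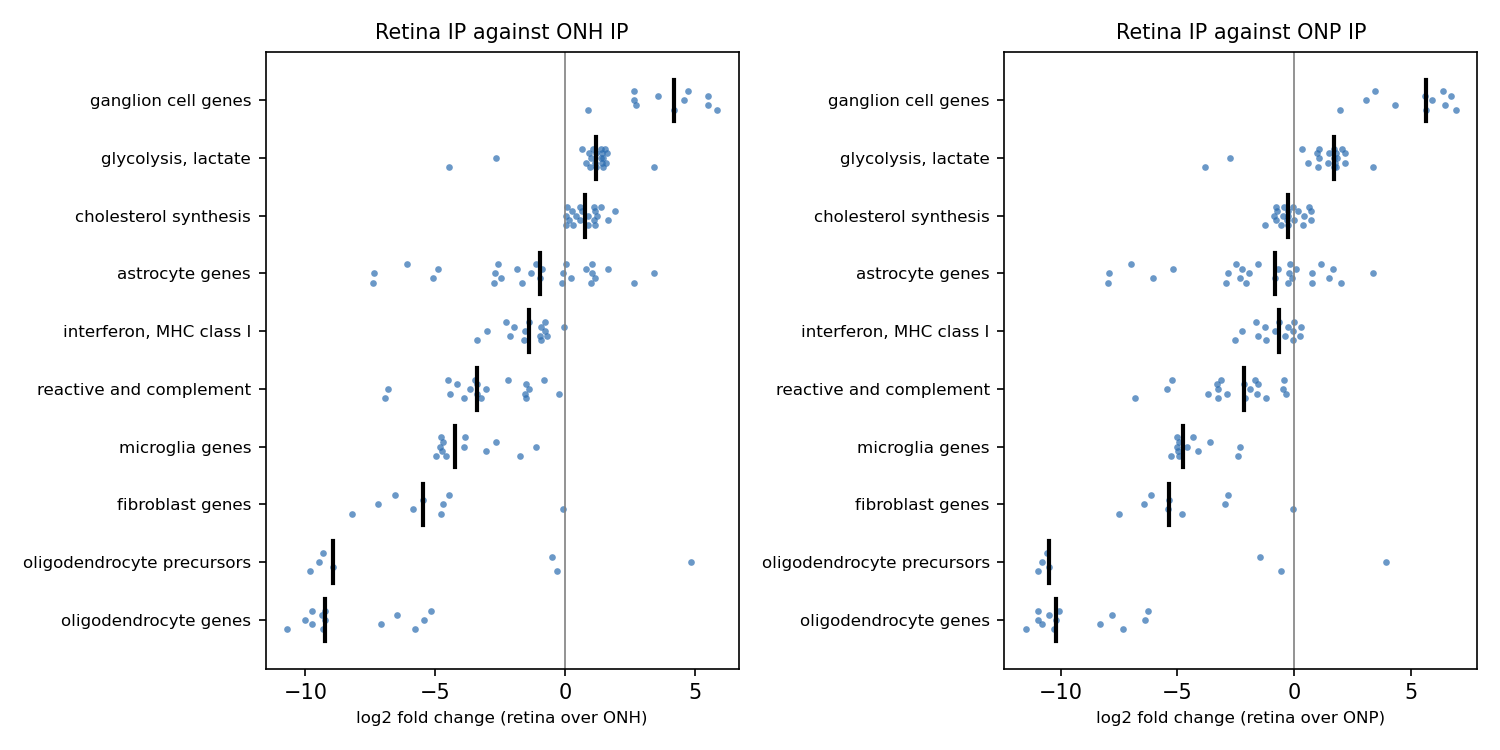
Log2 fold change of retina IP over ONH IP (left) and over ONP IP (right) for each measured member of 10 gene lists, with list medians as black bars; members with 3 or fewer counts in a group are left out. Ganglion cell and glycolysis genes lie mostly above 0, and oligodendrocyte genes lie below it in both panels.

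Genes that set retina apart from both optic nerve regions were taken as the overlap of these calls. Genes were named only where the retinal libraries did not overlap those of either region. Of the 10 such higher genes with the largest differences, 6 averaged higher in retinal IP than in input and 4 lower. Angpt4, Cd36, Ackr2 and Pax8 were higher in IP, with log2 fold changes of 3.60, 2.89, 3.29 and 2.89 (adjusted p = 0.057, 0.057, 0.0676 and 0.057, none past edgeR's test). DESeq2 and a fit of all 26 libraries called these 4 higher in IP. C1ql4, a complement-related gene (2.98, adjusted p = 0.0936), and the claudin gene Cldn10 (1.83, adjusted p = 0.192) averaged higher without passing edgeR's test, and DESeq2 and the fit of all 26 libraries called C1ql4. The neuronal RNA-binding protein gene Elavl2 and the neuropeptide gene Adcyap1 averaged lower in IP than in input (-0.81 and -0.26, adjusted p = 0.254 and 0.785), Adcyap1 with a sign that turned under quality weights, as did the transcription factor genes Pou4f3 (-0.50, adjusted p = 0.462) and Eomes (-0.40, adjusted p = 0.638). In the lower set, the 10 largest differences without such overlap included the oligodendrocyte gene Opalin, the protease gene Klk6 and the connexin gene Gjc3. Each was more than 10 log2 units lower against both regions. In Itih3, a hyaluronan-binding protein gene of astrocytes, 2 counts in retina stood against 19871 in ONH and 11119 in ONP, ratios of 8370 (95% counting interval 2320 to 69100) and 5100 (1410 to 42100).

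In all, 1523 genes were higher in retina than in both regions and 2626 lower (edgeR, adjusted p under 0.05 in both tests), and without ONP replicate 7 these were 379 and 1420. Independent lists of those sizes would share 269 and 687 genes. Simulated unchanged groups against the shared retinal libraries gave a median of 0 in each direction over 20 simulations. Few genes can be called in such groups, so this count cannot show what sharing the retinal libraries adds. Log fold changes against ONH and against ONP correlated at 0.9089, with a median of 0.8315 in the simulations. In the simulations both comparisons shared the retinal libraries and the batch term, so a high correlation arose without any change between groups. The covariance was 3.933, with a median of 0.4566 in the simulations. Without shared retinal libraries, in sets of 3, the medians were 0.691 for the correlation and 3.688 for the covariance. Those fits had separate batch terms as well, so the lower correlation cannot be credited to the retinal libraries alone. With the retinal libraries split into sets of 3, the overlap had a median of 246 higher and 904.5 lower genes, where independent lists would share 37.7 and 221. Of the higher set, 193 of 1521 genes tested were above input at an unadjusted p under 0.05 and 113 below it, where 1771 and 1585 of all 15181 genes were. Of the lower set, 220 of 1854 were above input and 174 below it.

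The fourth comparison asked how IP RNA of the ONH differed from that of the ONP. No optic nerve input was sequenced, so enrichment for astrocyte RNA was not measured there. In batch 1, Mbp averaged 23650 CPM in ONH and 41710 CPM in ONP, above Gfap at 12390 and 15270 CPM. Whether the differences below lie in astrocytes or in other cells carried along was not tested. All rod genes and most pigment cell genes measured rose in ONH, as did some genes of retinoid handling and eye development, and most cholesterol synthesis genes and some oligodendrocyte precursor genes fell. Cartpt, a neuropeptide gene, rose by 7.39 (adjusted p = 4.94e-05), from 8.10 CPM in ONP to 1333 CPM in ONH. The melanosome gene Mlana rose by 7.58 (adjusted p = 0.000415) and the eye-field factor gene Vax2 by 2.36 (adjusted p = 0.000349). Efna5, an axon guidance ligand, rose by 1.95 (adjusted p = 7.84e-05) and tenascin C (Tnc), a matrix glycoprotein, by 2.67 (adjusted p = 0.00656). Rlbp1 rose by 1.55 (adjusted p = 0.024). The call of Rlbp1 ended without ONH replicates 1, 3 or 7 or ONP replicates 2, 4 or 7 (adjusted p from 0.0507 to 0.0603). Among genes with no overlap between ONH and ONP libraries, the largest decreases were in Cidea and Ucma. Cidea is a lipid droplet gene (-2.27, adjusted p = 0.00414). Ucma is a matrix protein gene (-2.21, adjusted p = 0.00449, but 0.0585 in a fit of all 26 libraries, the highest of its alternatives). Gpr17 and Neu4, both of oligodendrocyte precursors, fell with log2 fold changes of -1.81 (adjusted p = 0.000697) and -1.66 (adjusted p = 0.00604).

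Cholesterol synthesis had 17 of 20 members lower in ONH over all genes and 19 when adjusted over the list alone, with 0 higher (camera adjusted p = 2.47e-19, and 0.21 with an estimated correlation). Dhcr7, which makes cholesterol from its precursor, fell with a log2 fold change of -1.43 (adjusted p = 0.00115) and squalene epoxidase (Sqle) with one of -1.17 (adjusted p = 0.00117). Oligodendrocyte precursor genes had 4 of 8 members lower over all genes and 7 when adjusted over the list alone (camera adjusted p = 1.44e-07, and 0.21 with an estimated correlation). Oligodendrocyte genes had 1 of 13 lower over all genes and 9 when adjusted over the list alone (camera adjusted p = 3.74e-09, and 0.304 with an estimated correlation). Pigment cell genes had 9 of 10 members higher, also when adjusted over the list alone, among them the pigment enzyme gene Dct (4.80, adjusted p = 0.000141), with a camera adjusted p of 1.27e-11, and 0.234 with an estimated correlation. Retinoid genes had 6 of 16 members higher over all genes and 8 when adjusted over the list alone (camera adjusted p = 2.5e-05, and 0.21 with an estimated correlation). Eye-field and glial transcription factors had 8 of 29 members higher and 2 lower over all genes, and 9 and 3 when adjusted over the list alone (camera adjusted p = 0.00424, and 0.349 with an estimated correlation). Immediate-early and stress genes had 3 of 12 members higher over all genes and 5 when adjusted over the list alone, such as Ier2 (1.22, adjusted p = 0.0118), with a camera adjusted p of 0.00246, and 0.366 with an estimated correlation. Interferon and MHC class I genes had 1 of 15 members higher, also when adjusted over the list alone (camera adjusted p = 0.000263, and 0.446 with an estimated correlation).

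All 15 rod genes rose in ONH, also when adjusted over the list alone (camera adjusted p = 1.69e-18, and 0.234 with an estimated correlation). In batch 1 alone, which leaves out both bridging libraries, the rod list kept its direction and passed (camera adjusted p = 6.68e-06). Bipolar cell genes had 7 of 11 members higher over all genes (camera adjusted p = 2.85e-06, and 0.258 with an estimated correlation), and in batch 1 alone the list did not pass. The general astrocyte markers did not separate the regions. Gfap (-0.44, adjusted p = 0.561), S100b (0.21, adjusted p = 0.827), Slc1a3 (0.53, adjusted p = 0.446), Aldh1l1 (-0.13, adjusted p = 0.869) and Glul (-0.02, adjusted p = 0.974) did not pass, the last with a sign that turned under limma-voom and under a replicate block. Pax2 (0.61, adjusted p = 0.543), Pax8 (adjusted p = 0.257), Aqp4 (-1.08, adjusted p = 0.145), Pdgfra (-0.90, adjusted p = 0.193) and Mbp (-0.93, adjusted p = 0.15) did not pass either. In batch 1 alone Aqp4 (-1.02, adjusted p = 0.0297) and Pdgfra (-0.75, adjusted p = 0.0225) did.

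edgeR called 725 genes higher and 498 lower in ONH than in ONP, of 16355 tested, and 1264 and 1181 in batch 1 alone. Without ONH replicate 1 the counts were 409 and 192, without ONH replicate 3 they were 421 and 219, without ONP replicate 2 they were 479 and 274, and without ONP replicate 4 they were 457 and 263. The count of lower genes was 305 without ONH replicate 5, 284 without ONP replicate 1 and 281 without ONP replicate 6.

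**Figure D4:**
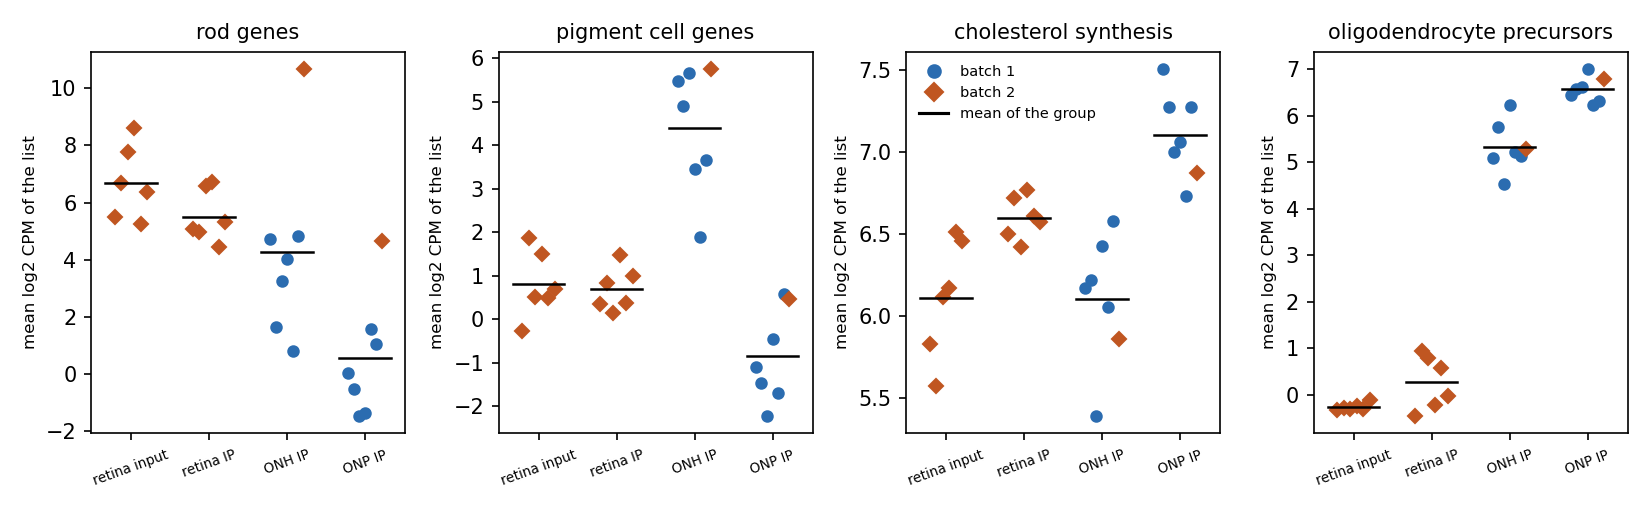
Mean log2 CPM of 4 gene lists in every library, by group, with circles for batch 1, diamonds for batch 2 and lines for group means. Rod and pigment cell genes were higher in ONH than in ONP, and cholesterol synthesis and oligodendrocyte precursor genes were lower.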

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

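The tests of the rod transcripts and of the uneven retinal IP libraries were chosen after the results were seen, as were the tests of sex and the regrouping tests for retina IP against input and against ONH. The test of transcript length and the other regrouping tests were written before.

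The bridging ONH library carried rod and cone transcripts far above the other ONH libraries, with a median rod gene at 2110 CPM against 9.32 CPM in the others and 20.6 CPM in the bridging ONP library. The tables argue against retinal tissue of the make-up of the input, since the rod genes would need 10.7 times the whole input level, and against a wrong label, since Mbp was 230-fold the highest retinal library. A piece of photoreceptor-rich outer retina in the dissection may account for part of it, as rod genes rose 28.3 times as much as ganglion cell genes. Bipolar genes (42.1-fold) and amacrine and horizontal cell genes (16.1-fold) of the inner retina were raised as well, so which tissue was present stays open.

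Oxidative phosphorylation and ribosomal protein genes were higher in the bridging libraries than in batch 1, for 37 of 45 genes in ONH and 33 of 45 in ONP. For transcript length the test cannot tell: the excess over 200 genes of the same length was at least 0.802 of the difference, but its quartiles in ONP ran from -0.164 to 1.38. Sex cannot be told apart from batch either, because 4 Y-linked genes summed to at least 702 counts in every batch 1 library and to at most 1 in batch 2. The batch term therefore also holds any difference of sex, and 702 against 1 leaves no library to separate them.

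Astrocyte transcripts were uneven between the retinal IP libraries, with Pax8 from 30.2 to 377 CPM. Replicates 1, 5 and 6 had ganglion cell genes near the input level. Their ganglion cell ratios were 0.982, 1.13 and 1.14, while their highest share of the lowest input's mitochondrial RNA was 0.138. These values argue against RNA of the input's make-up as the source of the ganglion cell transcripts in those libraries. Carry-over that leaves mitochondrial RNA behind was not tested. Replicates 2, 3 and 4, with the most Pax8, had shares of 0.369, 0.758 and 0.798. The share therefore did not follow the ganglion cell genes. The tables argue against exchanged labels, because the highest input Pax8 was 0.11 of the median of the 3 highest IP libraries. What sets these libraries apart stays open, and no biological explanation was tested.

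For retina IP against input the real count was 0, so all 100 of 100 splits had to call as many, and the number of genes called says nothing about chance. The highest other split called 238, which may point to a structure of the samples, but 99 of the 100 splits called none and no such structure was tested. For ONH against ONP 1223 genes were called, with 1 in the highest other split, and 1 of 100 splits was as large, the real one. These splits also moved the bridging libraries and did not keep libraries of the same replicate number together. They exclude chance only for groupings that ignore batch and such pairing. The real grouping was also the only 1 of 100 as large for retina against ONH (5532, highest other 314), retina against ONP (5371, highest other 1081) and retina against both (4149, highest other 1). The splits of these 3 moved libraries between the batches, so they exclude chance only for groupings that ignore batch, not within a batch, where retina against ONH or ONP leaves only 7 arrangements.

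Single libraries stood apart in 19 of 108 groups of values checked, where 5.4 would be expected by chance at 1 in 20. The bridging ONH library had 0.4241% mitochondrial counts (next 0.2705%) and the bridging ONP library 0.5912% (next 0.1896%). S100b was 2069 CPM in the bridging ONP library (next 1230). In mean log2 CPM, the bridging ONH library had astrocyte genes at 7.939 (next 8.746), rod genes at 10.68 (next 4.819), cone genes at 6.804 (next 1.353), bipolar genes at 5.203 (next 0.74) and amacrine and horizontal cell genes at 2.798 (next -1.118). Cone genes in the bridging ONP library were at 0.9742 (next -1.353).

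Retina input replicate 2 had Glul at 4122 CPM (next 1382), S100b at 788.2 CPM (next 240.2) and microglia genes at a mean log2 CPM of 5.451 (next 4.063). Pax8 was 10.46 CPM in ONH replicate 1 (next 4.52) and 4.396 CPM in ONP replicate 1 (next 1.518), whose fibroblast genes were at 7.327 (next 5.364). In replicate 5, microglia genes were low in ONH (3.909, next 6.113) and in ONP (4.082, next 6.419), as were fibroblast genes in ONH (4.78, next 5.957) and oligodendrocyte genes in ONP (9.352, next 10.68).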

How the results depend on the processing

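Alternatives without retina input replicates 1 and 2, without the bridging libraries, without ONH replicate 7 for the lists, with quality weights, and with the added condition against input were chosen after the results were seen. Where a value changed, the cause was not tested.

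For retina IP against input, the counts of 0 higher and 0 lower became 152 and 41 without the low-count filter, 969 and 1103 with DESeq2, 1419 and 1452 with all 26 libraries, 1 and 48 without input replicates 1 and 2, and 474 and 566 with quality weights. Leaving out 1 library gave 0 to 341 higher and 0 to 40 lower. Aqp4 turned to -0.0005867 with RLE, -0.0009356 with DESeq2 and -0.005789 without input replicates 1 and 2, and Adcyap1 to 0.01404 with quality weights. The ganglion cell list had an adjusted p of 0.0652 without input replicates 1 and 2.

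For retina against ONH, 2080 higher became 1242 with all 26 libraries, 3871 without a batch term, 121 in batch 2, 437 with only the groups compared and 4704 without the bridging libraries. The 3452 lower became 697 in batch 2 and 1632 with only the groups compared. Leaving out 1 library gave 722 to 2442 and 2262 to 3648. S100b turned to 0.1968 in batch 2 and 0.04523 with only the groups compared. Without a batch term Slc1a3 turned to -0.4872, Aldh1l1 to -1.114 (called lower, adjusted p = 0.0412) and the rod list upward (adjusted p = 0.171). Without the bridging libraries Slc1a3 turned to -0.6233 and Aldh1l1 to -1.247 (called lower, adjusted p = 0.0158), and Gfap was called lower (-2.825, adjusted p = 4.93e-05). Aldh1l1 was -0.1798 with limma-voom.

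For retina against ONP, 2116 higher became 4225 without a batch term, 783 in batch 2 and 4747 without the bridging libraries, and 3255 lower became 907 in batch 2. Leaving out 1 library gave 567 to 2436 and 1588 to 3380. Aldh1l1 turned to -0.2859 with limma-voom, -1.253 without a batch term and -1.388 without the bridging libraries (the last 2 called lower, adjusted p = 0.0226 and 0.00831), where Slc1a3 was -0.1198. The hypoxia and angiogenic list had an adjusted p of 0.0416 without the filter, and the list of eye transcription factors had an adjusted p of 0.138 without ONH replicate 7.

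For ONH against ONP, 725 higher became 1150 with DESeq2, 385 with all 26 libraries and 1264 in batch 1. The 498 lower became 320 without the filter, 891 with DESeq2, 126 with all 26 libraries, 1181 in batch 1 and 228 at 2-fold or more. Leaving out 1 library gave 409 to 869 and 192 to 697. Glul turned to 0.01782 with limma-voom.

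The 1523 genes higher than in both regions became 920 with all 26 libraries, 3194 without a batch term, 102 in batch 2, 351 with only the groups compared, 3889 without the bridging libraries and 193 when also above input. The 2626 lower became 403 in batch 2, 1075 with only the groups compared and 3973 without the bridging libraries. Leaving out 1 library gave 379 to 1820 and 1420 to 2762.

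The replicate block gave 0 and 0 against input, and in place of the batch term 4601 and 4853 for ONH, 4808 and 4891 for ONP, 699 and 589 between ONH and ONP, and 3943 and 4115 for both. It ties retinal libraries 1 to 6 to optic nerve libraries of batch 1. These are not the same animals, since 4 Y-linked genes summed to at least 702 counts in batch 1 and at most 1 in batch 2. Against ONH and ONP the block therefore shows a fit without batch adjustment, not pairing. Under this block Slc1a3 was -0.7941 and -0.2106 and Aldh1l1 -1.397 and -1.537 against ONH and ONP (called lower, adjusted p = 0.0113 and 0.00656), Gfap was called lower against ONH (-2.943, adjusted p = 5.1e-05), the rod list turned upward against ONH (adjusted p = 0.00341), and Glul was 0.0278 between ONH and ONP. Pairing by replicate number was checked, and ONH and ONP libraries of the same number correlated at 0.0619 to 0.459, 6 of the 7 pairs over 0.1. Every ONH library correlated best with the ONP library of its own number, while ONP libraries 1, 3 and 4 correlated best with ONH library 2, so the data hold a hint of pairing that the labels do not settle.

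Of the calls of named genes, those of Pax8 (limma-voom, 0.0546) and of Aqp4 (all 26 libraries 0.0814, only the groups compared 0.262), Rlbp1 (0.35), Glul (0.0833) and Cd36 (0.0617, these 3 with only the groups compared) ended against ONH. Against ONP those of Gfap (RLE 0.0589, no filter 0.0815, all 26 libraries 0.125, only the groups compared 0.122), Pdgfra (0.0545) and Glul (0.0879, both with only the groups compared) ended. With only the groups compared, log2 fold changes against ONH were -1.641 for Aqp4, 1.384 for Rlbp1, 1.671 for Glul and 8.283 for Cd36. Against ONP they were -1.822 for Gfap, 3.623 for Pdgfra and 1.76 for Glul. All kept their direction, and that of Rlbp1 shrank the most. Pax2 was called against ONP with RLE, DESeq2 (0.0124), no batch term (0.0123) and without the bridging libraries (0.017), and Slc1a3 with DESeq2 (0.0324). Between ONH and ONP the calls of Rlbp1 (without the bridging libraries, 0.0598) and Ucma (all 26 libraries, 0.0585) ended. In batch 2 alone Pax8, Aqp4, Pdgfra, Rlbp1, Glul, Angpt4 and Slc6a11 lost their calls against both regions, Cd36, Ackr2, Aldoc and Nefm against ONH, and Gfap, Adm, Vegfa and Slc1a2 against ONP. With 1 library per optic nerve region this fit has little power, so these losses do not show that the calls depend on batch. Folds such as those of Pax8 (7.656 against ONH, 8.179 against ONP) and Pdgfra (5.564 and 3.784) kept about their size. That of S100b against ONH changed sign (0.1968). Folds of like size cannot decide the question either, because the main fit takes its batch term from the same bridging libraries. Numbers in brackets are adjusted p.

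Over all settings other than the omission of single libraries, 1049 gene values stayed the same, 73 became stronger, 36 weaker and 21 turned. With an estimated correlation no list passed.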

Other observations

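Wnt pathway genes were lower in retina than in ONH for 9 of 20 members over all genes and 10 when adjusted over the list alone (camera adjusted p = 0.00364, and 0.258 with an estimated correlation). Pericyte and smooth muscle genes had 7 of 9 members lower in retina than in ONH (camera adjusted p = 0.00247, and 0.257 with an estimated correlation) and 6 of 9 lower than in ONP (camera adjusted p = 0.00537, and 0.258 with an estimated correlation), with 1 higher in each. Antioxidant and metal-handling genes had 10 of 20 members lower and 1 higher in retina than in ONP (camera adjusted p = 0.0126, and 0.447 with an estimated correlation).

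Slc6a11, a GABA transporter, averaged 371.2 CPM in retina IP, 79.65 in retina input, 23.78 in ONH and 36.5 in ONP. Vax2 averaged 97.86 CPM in retina IP and 113 in input, and stood at 15.31 in ONH and 1.95 in ONP.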
